A study of Mus musculus with 24 samples.

How the data were processed

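Poly-A RNA was sequenced from 24 whole guts of mouse embryos at embryonic day 12.5. The guts came from 4 genotypes: wildtype, Ret null, Sema3d null and Ret-Sema3d double null, on a mixed background of C57BL/6, 129/Sv and C3H strains. Each genotype was represented by 3 female and 3 male guts. Per the labels' protocols, each gut gave a stranded mRNA library that was sequenced as 100 bp read pairs on an Illumina HiSeq instrument.

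Per the submitters' processing notes, the authors used FastQC 0.11.5, Trimmomatic 0.36, STAR, RSEM 1.2.31 and DESeq 1.24.0, with the GRCm38 (mm10) build; the notes list the names without roles or order, and the STAR version is not given in the sources used here. The 4 deposited tables hold the authors' comparison results per gene and no value per library. The values used were of 3 kinds. The log2 coefficients of the intercept, sex and genotype terms are those the authors deposited, as named in the file headers. The deviances of a reduced and a full model, deposited by the authors, have no fixed range and were used as a score of fit. The coefficients of the interaction table are log2 coefficients too, although a few unbounded fits lie beyond the range such values can take. The p-values and adjusted p-values were deposited by the authors for the term that the reduced model lacks. One table each compares Ret null, Sema3d null and double null guts with wildtype, over 12 guts with sex as a covariate. The fourth table fits all 24 guts with sex, Ret, Sema3d and their interaction, and its p-values test the interaction. In the Ret null table the headers of the gene symbol and gene type columns are exchanged, and the columns were read by their content.

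The tables were checked before use. Deposited p-values equalled the chi-square tail (1 degree of freedom) of the difference of the deviances within 4.91e-09, and deposited adjusted p-values equalled the Benjamini-Hochberg adjustment over each table. The base of the logarithm is not named in the headers. With base 2 the fitted wildtype levels summed to between 11.6 and 12.0 (in units of 1e6 normalised counts) per table, and with the natural base to between 432 and 458 in the same units. Base 2 was used, as the natural base gives totals far above the sequencing depth aimed at per the labels' protocols. The depth of each library is unknown from these tables.

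From the deposited values a standard error was derived for each coefficient, as its size divided by the square root of the deviance difference. This derived error follows every value given after ±, and the 95% intervals drawn in the plots rest on it. In simulated counts for the Ret null comparison (12 guts, 2000 genes at the fitted levels, 200 of them changed), the derived error was 1.01 times the model's own error at the median of called genes, and 93% of genes changed by 1 log2 unit were called. For the interaction (24 guts, 2000 genes), 84% of genes changed by 1 log2 unit and 98% of those changed by 2 were called. The 95% intervals held the true value for 91.4, 87.1, 91.3 and 89.6% of called genes in the simulated Ret null, Sema3d null, double null and interaction tables, and for 94.5, 94.9, 95.5 and 94.5% of all genes. Of the simulated calls, 2.53, 6.67, 3.88 and 5.70% were unchanged genes. These simulations took the dispersion as known, so they bear on the arithmetic and not on the authors' dispersion estimates. The deposited p-values of the strongest genes are listed as 0, and their adjusted p was therefore recomputed from the deviances. A coefficient beyond 15 on the log2 scale was read as a fit against a group at about 0. No fold change was taken from such a coefficient, or from a model that did not converge. The fitted level of a gene is 2 to the power of the intercept, averaged over the sexes and multiplied by the change in each genotype.

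Genes were called at the authors' deposited adjusted p below 0.05. No count test was run, since the tables hold no counts; the tests of double null against either single null, planned for the case that libraries were given, were not run for the same reason. The authors deposited no p-value for sex, so sex is described by its coefficient. The text names, for each comparison with wildtype, Ret and Sema3d, the 12 largest increases and 12 largest decreases among called genes with a fitted level of at least 50 in either genotype, and up to 4 genes with the smallest p in each gene list described; for the interaction Ret, Sema3d and the 20 smallest p; and for sex 10 autosomal and 10 sex-linked genes by coefficient. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here. These rules, and the 21 gene lists with their 388 entries were fixed before the data were examined, and 20 genes stand in more than 1 list.

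Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed square root of the deviance difference, which is the signed normal quantile of the p-value, with a preset correlation between genes of 0.01 and again of 0.05, and adjusted by Benjamini-Hochberg over the 21 lists. They were also tested on ranks, and without Ret, Sema3d and the genes that stand in more than 1 list. A correlation could not be estimated without libraries, so the list tests take genes of 1 cell type as nearly independent. In simulated values for the double null comparison (10000 genes), 10 of 10 shifted lists and 0 of 10 unshifted lists were called. These values were drawn independently per gene, so they do not test lists whose genes move together. Bootstrap intervals of list medians drew genes 10000 times and cover the spread between genes only. Positions, transcript lengths and GC contents came from GENCODE M21 on GRCm38, in which 99.3% or more of each table's identifiers were found after removing the version suffix. A smooth trend of the coefficient with the log of transcript length and GC content was fitted to protein-coding genes with a level of at least 50 and removed as an added alternative. For differences between groups in the 24-gut fit, which have no derived error, genes were weighted there by the error of the interaction divided by the square root of 2. Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 were used. The labels name separate guts but no litter, dissection day or sequencing batch, so these could not be tested, and p-values measure the spread between the guts of this series.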

Results

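The series asked whether Ret and Sema3d interact in the development of the enteric nervous system, the nerve cells and glia of the gut wall that arise from migrating neural crest cells. Ret encodes the receptor tyrosine kinase for GDNF-family ligands, and Sema3d encodes a secreted semaphorin, a class of guidance cues. RNA from 24 whole guts of embryonic day 12.5 was sequenced, 6 guts per genotype and 3 per sex. The deposited values are the authors' model fits, one table per comparison; values per gut and the depth of each library are unknown from them. The tables list between 24602 and 26260 genes, of which 12242 to 12425 had a fitted level of at least 50 normalised counts. At that level the median derived error of a log2 change was 0.0776 for Ret null, 0.111 for Sema3d null, 0.0788 for double null and 0.136 for the interaction.

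The targeted genes were examined first. Ret lies on chromosome 6 (GRCm38, 118151745 to 118197718, minus strand) and is listed as ENSMUSG00000030110.13. In the authors' deposited table for Ret null guts its log2 change was -8.34 ± 0.24 (adjusted p from the deviances 2.11e-256), and in the one for double null guts -10.36 ± 0.29 (3.66e-279). In the 24-gut fit of the authors' deposited table, Ret fell from a level of 1523 in wildtype to 0.310% of it in Ret null and 0.0758% in double null guts. Sema3d (ENSMUSG00000040254.11) lies on chromosome 5 (12383385 to 12588948, plus strand). Its log2 change was -1.06 ± 0.11 in Sema3d null guts (adjusted p 6.49e-19) and -1.04 ± 0.07 in double null guts (3.29e-51) in the authors' deposited tables. The fitted Sema3d level was thus 47.7% and 48.5% of wildtype, and the gene-level values do not show which exons remained. Each gene was also measured in the other null. Sema3d was lower in Ret null guts in the authors' deposited table, by a log2 change of -0.27 ± 0.06 (adjusted p 8.82e-04), while Ret in Sema3d null guts had -0.19 ± 0.11 (adjusted p 1.000).

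Ret null guts were compared with wildtype guts to ask what the loss of Ret does alone. Genes of the neural crest lineage, enteric neurons and glia were lower, and few genes were higher. The authors' deposited table called 654 genes, 559 lower and 95 higher, and 2074 genes had an unadjusted p under 0.05. Neuronal genes were strongly reduced on the log2 scale, with Tubb3, a neuronal tubulin, at -5.36 ± 0.12, Chrna3, a nicotinic acetylcholine receptor subunit, at -6.18 ± 0.21, and Dbh, which makes noradrenaline, at -6.28 ± 0.34 in the authors' deposited table.

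The enteric neural crest and progenitor list had 16 of 20 measured genes lower, the targeted Ret itself among them, and 0 higher. Adjusted over the list alone, 17 were lower. The list had a median log2 change of -1.20 (95% bootstrap interval -3.80 to -0.41). Its list test gave adjusted p = 8.69e-223 with a correlation of 0.01 and 1.74e-137 with 0.05. L1cam, a cell adhesion protein, changed by -3.82 ± 0.13 in the authors' deposited table. The enteric neuron list had 31 of 36 genes lower (33 adjusted over the list alone) and a median of -2.50; in the authors' deposited table Elavl3, a neuronal RNA-binding protein, changed by -5.42 ± 0.19 and Celf3 by -3.91 ± 0.14. The adjusted p of that list was 1.76e-217 with a correlation of 0.05. The synapse and neurotransmission list had 20 of 30 lower (22 adjusted over the list alone; list adjusted p = 7.49e-77), including Chrnb4 at -4.49 ± 0.19 and the synaptic vesicle calcium sensor Syt1 at -2.69 ± 0.13 in the authors' deposited table. Stmn3 at -5.83 ± 0.36 and the homeobox gene Tlx2 at -5.94 ± 0.29 were also among the 12 largest decreases in the authors' deposited table.

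The glia list had a smaller median reduction than the neuron list, though some of its members fell beyond the neuron list median of -2.50. In the enteric glia and Schwann lineage list 10 of 20 genes were lower (11 adjusted over the list alone), with a median of -0.74 and a list adjusted p of 2.66e-40. Sox10, the transcription factor of crest progenitors and glia, changed by -3.50 ± 0.21, Foxd3 by -3.78 ± 0.25 and Cdh19 by -3.09 ± 0.23 in the authors' deposited table, while Erbb3, a neuregulin receptor, changed by -0.85 ± 0.06. Of the 28 genes of the Ret and Ednrb pathway and Hirschsprung list, 10 were lower and 1 was higher (13 and 2 adjusted over the list alone; list adjusted p = 1.78e-52). Without Ret, Sema3d and the genes it shares with other lists, its adjusted p was 0.0487. Ednrb, the endothelin receptor of crest cells, changed by -1.17 ± 0.06, and the gene that rose was Gdnf, which encodes the Ret ligand made by gut mesenchyme, at 0.36 ± 0.08 (adjusted p 2.21e-04) in the authors' deposited table; Gdnf was named after its value was seen.

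Among 31 semaphorins and their receptors, 3 were lower and 1 higher (4 and 3 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.578). The plexin Plxna4 changed by -1.45 ± 0.10, the semaphorin co-receptor Nrp1 by -0.24 ± 0.05 and Nrp2 by 0.17 ± 0.04 in the authors' deposited table, beside Sema3d. Lists of other gut cell types held few calls. Etv1, which stands in the progenitor list as well as the interstitial cell and fibroblast list, was lower at -0.35 ± 0.09 in the authors' deposited table. Aldh1a2, a retinoic acid synthesis enzyme in the mesothelium list, was higher there at 0.28 ± 0.08. In 13 lists 0 genes were called by the authors' deposited table, with 22 of their 195 measured genes at an unadjusted p under 0.05. These were smooth muscle, gut epithelium, endothelium, erythroid, macrophage, cell cycle, hypoxia, apoptosis, Y-linked, X-linked and 3 lists of neighbouring organs or tissue. Adjusted over the list alone, 3 macrophage and 2 hypoxia genes were lower and 1 cell cycle gene was higher. The macrophage list passed as lower (median -0.23, adjusted p = 0.0311) with a correlation of 0.01 and not with 0.05 (adjusted p = 0.112). The lists that did not pass in Ret null guts had adjusted p = 0.409 (smooth muscle), 0.916 (interstitial cell and fibroblast), 0.221 (epithelium), 0.578 (endothelium), 0.755 (erythroid), 0.0730 (mesothelium), 0.591 (pancreas and liver), 0.864 (kidney, gonad and adrenal), 0.578 (skeletal muscle and dorsal root ganglion), 0.0534 (cell cycle), 0.540 (hypoxia), 0.811 (apoptosis), 0.811 (Y-linked) and 0.896 (X-linked). On ranks the cell cycle and epithelium lists passed as higher (adjusted p = 0.00502 and 0.0379; medians 0.04 and 0.09).

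**Figure D1:**
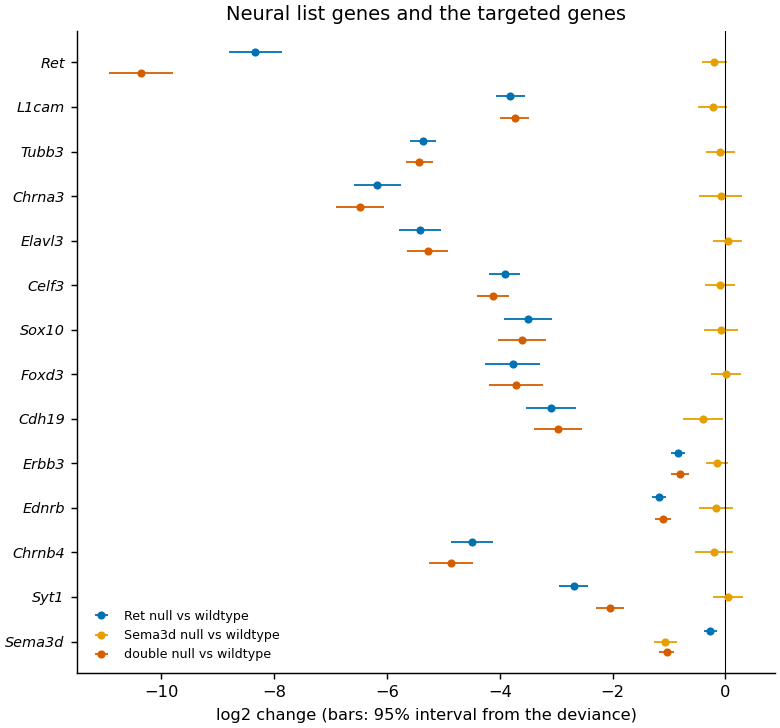
Log2 change from wildtype (x axis) of neural list genes and Sema3d in Ret null, Sema3d null and double null guts, from the authors' deposited tables. Points are the fitted changes and bars 95% intervals derived from the deviances; Chrna3 sits at -6.18 in Ret null, -0.09 in Sema3d null and -6.48 in double null guts.

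The largest increases in Ret null guts were mostly in pseudogenes and multicopy genes. In the authors' deposited table, the ribosomal protein pseudogenes Rps3a3 and Rps3a2 changed by 9.35 ± 1.23 and 6.40 ± 1.12, the histone gene Hist1h2ai by 1.95 ± 0.32, and the pseudogenes Gm10163, Gm21451, Gm10359 and Gm17383 by 3.28, 1.81, 1.60 and 1.36. Hist1h2ah was also among these 12, from a fit that did not converge. The remaining 4 were Gm4737 at 2.09, Gm14434 at 1.88, A530016L24Rik at 1.45 and 4921507P07Rik at 1.15 in the authors' deposited table. Reads of such copies can be assigned to either copy, so these values are uncertain, as are the decreases of Gm28635, Gm12191, Gm8210, Gm13841 and Gm3375, of which the first 2 were fitted against about 0. The median size of the 93 increases with converged and bounded fits was 0.321, against a median derived error of 0.0831.

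Sema3d null guts were compared with wildtype guts to ask what the loss of Sema3d does alone. Few genes were called beside Sema3d, 0 members of the neural lists among them, and endothelial genes were slightly higher as a group. The authors' deposited table called 10 genes, 5 higher and 5 lower, and 1122 genes had an unadjusted p under 0.05. Besides Sema3d these were Samd5 at -0.49 ± 0.11, the heme-binding protein gene Hebp1 at 0.88 ± 0.19, Gm9581 at -0.77 ± 0.16, Gm37194 at -0.72 ± 0.16, Rpl27-ps3 at 0.95 ± 0.22, Rps3a3 at 8.62 ± 1.44 and Rps3a2 at 5.62 ± 1.19 in the authors' deposited table, and the remaining calls, Gm28635 and Gm45234, were fitted against a group at about 0; Gm45234 falls outside the naming rule and was named after its value was seen. The derived errors were larger here: the smallest called change at a level of at least 50 was 0.489 on the log2 scale, against 0.154 in the Ret null table.

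In the neural lists the authors' deposited table for Sema3d null guts called 0 genes. An unadjusted p under 0.05 was found for 0 of 20 progenitor, 0 of 36 neuron, 3 of 20 glia and 3 of 29 synapse genes. L1cam had a log2 change of -0.23 ± 0.13 and Nrcam -0.38 ± 0.15 in the authors' deposited table, neither past the threshold. The progenitor list was lower as a group, with a median of -0.12 (interval -0.16 to -0.07; adjusted p = 0.0182), and did not pass with a correlation of 0.05 (adjusted p = 0.130) or without Ret, Sema3d and genes shared with other lists (adjusted p = 0.314). The neuron, glia and synapse lists had adjusted p = 0.30, 0.252 and 0.218. With the transcript length trend described for the interaction removed, the neuron list passed as lower (adjusted p = 0.0166, or 0.189 with a correlation of 0.05), and the progenitor list had adjusted p = 0.00724. The endothelial list was higher, with a median of 0.22 (interval 0.09 to 0.26) and adjusted p = 1.45e-05, or 0.00101 with a correlation of 0.05; 0 of its 15 genes passed singly or adjusted over the list alone. Eng, a TGF-beta co-receptor of vessels, had 0.25 ± 0.09 and Pecam1 0.22 ± 0.09 in the authors' deposited table. The pancreas and liver list was higher too, with a median of 0.49 and adjusted p = 3.85e-04 (0.0108 with 0.05).

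Further lists passed in Sema3d null guts with a correlation of 0.01 and not with 0.05. They were 4: mesothelium (adjusted p = 0.0428, then 0.145), macrophage (0.0428, then 0.166) and hypoxia (0.0428, then 0.166) as higher, and semaphorins and receptors (0.0417, then 0.166) as lower. None of these 4 passed after the transcript length trend described for the interaction was removed, or without Ret, Sema3d and genes shared with other lists. The lists that did not pass had adjusted p = 0.112 (Ret and Ednrb pathway), 0.435 (smooth muscle), 0.679 (interstitial cell and fibroblast), 0.342 (epithelium), 0.144 (erythroid), 0.323 (kidney, gonad and adrenal), 0.560 (skeletal muscle and dorsal root ganglion), 0.323 (cell cycle), 0.267 (apoptosis), 0.112 (Y-linked) and 0.112 (X-linked).

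Double null guts were compared with wildtype guts. The neural losses were of about the size seen in Ret null guts, and endothelial genes were higher. The authors' deposited table called 518 genes, 461 lower and 57 higher, with 1655 at an unadjusted p under 0.05. Tubb3 changed by -5.43 ± 0.12, Chrna3 by -6.48 ± 0.22 and Dbh by -5.44 ± 0.31 in the authors' deposited table. Other large decreases were Ina, a neuronal intermediate filament, at -5.31 ± 0.27, the peptide hormone Cck at -4.85 ± 0.49, Stmn3 at -5.86 ± 0.36 and Tlx2 at -5.23 ± 0.26 in the authors' deposited table. Of the progenitor list 16 of 20 genes were lower, the targeted Ret itself among them. Of the neuron list 32 of 36 were lower, of the glia list 10 of 20 and of the synapse list 20 of 30. Adjusted over the list alone, these lists had 17, 34, 12 and 21 genes lower, with 1 progenitor gene higher. Their medians were -0.98, -2.61, -0.67 and -1.13, and each list test passed with both correlations (largest adjusted p = 1.18e-23). Without Ret, Sema3d and genes shared with other lists, the progenitor list still passed (adjusted p = 5.89e-55). Glial genes in the authors' deposited table included Sox10 at -3.61 ± 0.22, Foxd3 at -3.72 ± 0.24 and Metrn at -0.85 ± 0.08. The Ret and Ednrb pathway list had 9 genes lower and 1 higher (11 and 2 adjusted over the list alone; list adjusted p = 1.44e-48), and Ednrb changed by -1.11 ± 0.07 in the authors' deposited table. Without Ret, Sema3d and the genes it shares with other lists, the pathway list did not pass (adjusted p = 0.106).

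Of 15 endothelial genes, 7 were higher and 0 lower in double null guts (11 higher adjusted over the list alone), with a median of 0.23 (interval 0.22 to 0.29; list adjusted p = 1.17e-11, or 4.11e-08 with a correlation of 0.05). The adhesion proteins of vessel walls Pecam1 and Cdh5 changed by 0.29 ± 0.06 and 0.28 ± 0.06, and the receptors Tie1 and Flt1 by 0.30 ± 0.07 and 0.47 ± 0.12 in the authors' deposited table. The 12 largest increases in the authors' deposited table included Flt1, Cd36 at 0.54 ± 0.12, Ecscr at 0.43 ± 0.13, Adgrf5 at 0.41 ± 0.07, Stab2 at 0.41 ± 0.11 and Icam2 at 0.39 ± 0.12. The others were 2610507I01Rik, 6030443J06Rik, Als2cl, Gxylt2, Rasgrp2 and Gm12191, the last from a fit that did not converge; Cd36 and 6030443J06Rik lie within 20 Mb of Sema3d. Plxnd1, a semaphorin receptor of endothelium, was higher at 0.22 ± 0.05 and Sema6d at 0.22 ± 0.06, while Plxna4 was lower at -0.88 ± 0.12 in the authors' deposited table. The semaphorin list had 2 genes higher and 2 lower, Plxna4 and the targeted Sema3d, and did not pass (adjusted p = 0.777). The mesothelium list was higher with 0 of 10 genes called and 3 at an unadjusted p under 0.05 (median 0.16, adjusted p = 0.0150, or 0.0448 with 0.05).

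In the authors' deposited double null table Etv1, of both the progenitor and interstitial cell lists, was lower at -0.35 ± 0.07. Calb1 of the kidney list was lower there at -1.78 ± 0.53, from a fitted wildtype level of 9.49. In 12 lists 0 genes were called by the authors' deposited table, with 9 of 175 genes at an unadjusted p under 0.05. The lists that did not pass had adjusted p = 0.263 (smooth muscle), 0.263 (interstitial cell and fibroblast), 0.263 (epithelium), 0.620 (erythroid), 0.777 (macrophage), 0.541 (pancreas and liver), 0.693 (kidney, gonad and adrenal), 0.693 (skeletal muscle and dorsal root ganglion), 0.340 (cell cycle), 0.515 (hypoxia), 0.777 (apoptosis), 0.964 (Y-linked) and 0.777 (X-linked). Tested on ranks in place of values, the smooth muscle, interstitial cell, epithelium and cell cycle lists passed as well (adjusted p = 0.0186, 0.00941, 0.0179 and 0.0139), the first 3 as higher and cell cycle as lower, with medians of 0.06, 0.08, 0.06 and -0.05. The interstitial cell list also passed without genes shared with other lists (adjusted p = 0.0473).

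**Figure D2:**
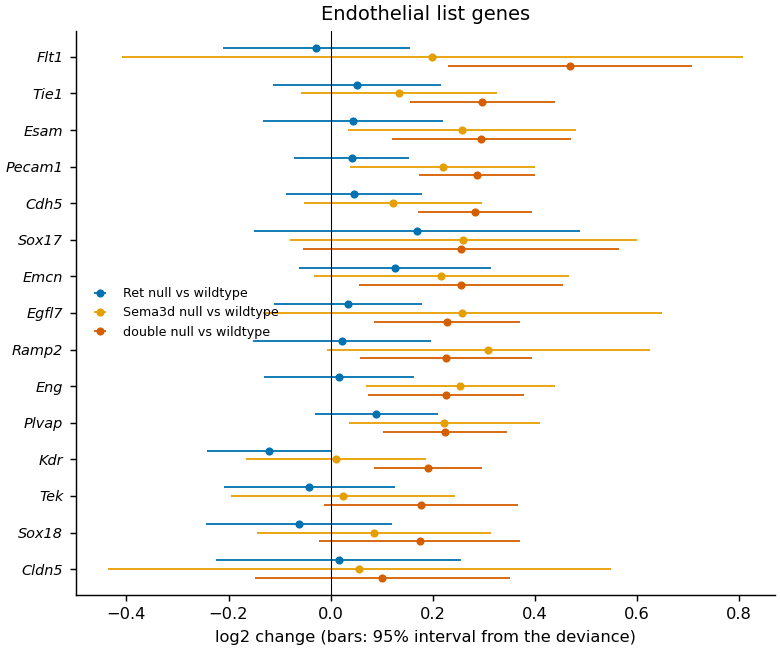
Log2 change from wildtype (x axis) of the 15 endothelial list genes in Ret null, Sema3d null and double null guts, from the authors' deposited tables. Points are fitted changes and bars 95% intervals derived from the deviances; the list medians were 0.03, 0.22 and 0.23 in that order.

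The Ret null and double null tables called many of the same genes: 404 were lower in both and 7 higher in both, and 1 was called in opposite directions. Among the 23948 genes tested in both, independent lists would share 10.8 lower and 0.226 higher genes. Both tables use the same wildtype guts, and 100 simulations of unchanged groups against shared controls gave 0 shared calls, a value that leaves out real effects and does not tell how many shared calls come from the controls, and a correlation of 0.501. The observed correlation of log2 changes across 12228 genes with a level of at least 50 was 0.902 (Spearman's rho 0.493), with a covariance of 0.107 against about 0.00306 from shared controls at the median derived error; genes are not independent replicates. The covariance is a mean over genes and the control value a median, so their ratio does not measure an excess over shared controls. The rank correlation of 0.493 was near the simulated 0.501. The simulated value is not a rank correlation and assumes equal errors in all groups and no length trend, so it cannot tell whether the ranks showed an excess. The controls could not be split, so part of the shared change may come from them. Of the 10 calls in Sema3d null guts, 6 were called in the same direction in Ret null guts. They included Sema3d itself, Gm28635, which was fitted against about 0, and the pseudogenes Rps3a3 and Rps3a2. In double null guts, where 9 of the 10 were tested, 2 were called in the same direction, Sema3d and Gm28635. Independent lists would share 0.117 lower and 0.0198 higher genes with Ret null guts. With such members, these counts do not tell of a shared response. The simulations gave 0 shared calls for these pairs too, with the same limit. The correlation of log2 changes with Ret null guts was 0.409 (simulated 0.4997, covariance 0.0287 against 0.00468). With double null guts it was 0.223 (simulated 0.4996, covariance 0.0139 against 0.00478). Both correlations lay below the simulated ones. Since the simulations assume equal errors in all groups and no length trend, no conclusion is drawn from that, and the covariances carry the limit given above.

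Over 633 genes called in Ret null guts with bounded fits in both tables, the log2 change in double null guts rose by 0.930 per unit of the change in Ret null guts (95% bootstrap interval over genes 0.885 to 0.983). Over the 502 genes called in double null guts the slope was 1.04 (0.992 to 1.08), so the side of 1 on which it fell followed the choice of genes. The covariance over the first set, a mean over genes, was 2.45, against 0.0122 from shared controls at the median error. In the 24-gut fit the enteric neuron list differed between double null and Ret null guts by a median of -0.07 (interval -0.21 to 0.0029), and the progenitor list by 0.04 (-0.05 to 0.12). The same difference had medians of 0.251 (0.0126 to 0.726) for erythroid, 0.167 (0.0728 to 0.257) for macrophage, 0.153 (0.0412 to 0.330) for hypoxia and 0.264 (0.0290 to 2.07) for pancreas and liver genes. Skeletal muscle and dorsal root ganglion genes had 0.178 (0.0147 to 0.516). Cell cycle genes were lower, at -0.0881 (-0.0934 to -0.0638), with 0 of 19 positive. These differences carry no p-value in the authors' deposited table. The neuron list was already low in Ret null guts (median -2.50), which limits how far a further loss could show in this difference or in the slope.

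**Figure D3:**
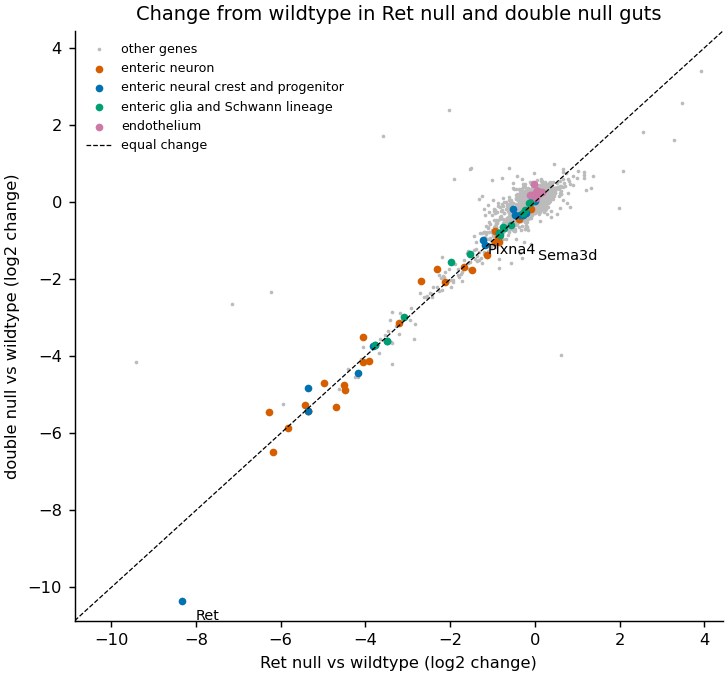
Log2 change from wildtype in Ret null guts (x axis) and double null guts (y axis), from the authors' deposited tables, for genes with a fitted wildtype level of at least 50 in the Ret null table. Coloured points are members of 4 gene lists and the dashed line marks equal change; neural list genes lie along it, and Ret lies at -8.34 and -10.36.

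The interaction of Ret and Sema3d, the departure of double null guts from the sum of the single null changes on the log2 scale, was tested over all 24 guts. Neural lists showed no interaction that passed, and genes called with a positive coefficient had longer transcripts than other genes at the median. The authors' deposited table called 43 genes, 34 with positive and 9 with negative coefficients; 1783 had an unadjusted p under 0.05. Of the 43, 10 were pseudogenes and 9 had a fit that did not converge or was unbounded. Ret had an interaction coefficient of -1.83 ± 0.60 (adjusted p 0.263) and Sema3d 0.29 ± 0.13 (0.636) in the authors' deposited table. Among the 20 smallest p, the genes with a bounded, converged fit and no pseudogene label included Lyst at 0.88 ± 0.18, the collagen gene Col12a1 at 0.74 ± 0.17, Klhl11 at 0.69 ± 0.15, Farp2 at 0.69 ± 0.15, Samd5 at 0.57 ± 0.13, the endoplasmic reticulum chaperone Pdia4 at 0.50 ± 0.11 and Birc6 at 0.45 ± 0.11 in the authors' deposited table. With the transcript length trend described below removed, Klhl11, Farp2 and Pdia4 were still called, while Lyst (coefficient 0.64, adjusted p 0.235), Col12a1 (coefficient 0.54, adjusted p 0.336), Samd5 (coefficient 0.40, adjusted p 0.451) and Birc6 (coefficient 0.20, adjusted p 1) were not.

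Plxna4 was the only list gene called, with an interaction coefficient of 0.66 ± 0.16 (adjusted p 0.0265) in the authors' deposited table; its fitted changes were -1.44 in Ret null and -0.88 in double null guts, and it was named after its value was seen. With the length trend removed it was no longer called (coefficient 0.47, adjusted p 0.537). In the other 20 lists 0 genes were called, with 34 of 353 genes at an unadjusted p under 0.05. Median interaction coefficients were 0.15 for progenitors (interval 0.04 to 0.26; list adjusted p = 0.319), 0.0015 for neurons (-0.16 to 0.07; 0.626), 0.06 for glia (0.366) and 0.04 for synapse genes (0.341). Some neural genes had little expression left in Ret null guts, such as Tubb3 (log2 change -5.36) and Chrna3 (-6.18). In such genes a further loss in double null guts would hardly show, so they cannot tell whether Sema3d loss adds to Ret loss. The median derived error of an interaction coefficient was 0.282 over the 391 genes lower in both Ret null and double null guts, so small interactions of single genes were not detectable. Their median coefficient was 0.135 (interval 0.0969 to 0.171), with 266 positive and 125 negative. Genes picked as lower against the shared wildtype guts lean toward positive values, so no conclusion is drawn from it. The semaphorin list passed as positive (adjusted p = 0.0226), but not with a correlation of 0.05 (adjusted p = 0.386) or after the length trend was removed (0.273). The remaining 16 lists had adjusted p from 0.319 to 0.706.

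Coefficients varied with transcript length in all 4 tables. Over 11942 protein-coding genes with a level of at least 50, the interaction coefficient had a Spearman's rho of 0.530 with transcript length and -0.364 with GC content. Its median was -0.14 in the shortest and 0.16 in the longest sixth of genes. The rho with length was -0.495 in Sema3d null, -0.220 in Ret null and 0.090 in double null guts, and 0.321 for double null minus Ret null in the 24-gut fit, across genes, which are not independent replicates. Among the 34 interaction calls with converged and bounded fits, the 27 with positive coefficients had a median transcript length of 7691 bases and the 7 with negative coefficients 1355, against 3604.5 for the genes tested. With the trend removed, an alternative chosen after seeing the data, 16 genes were called for the interaction, all among the 43, while 636, 10 and 522 were called in Ret null, Sema3d null and double null guts.

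**Figure D4:**
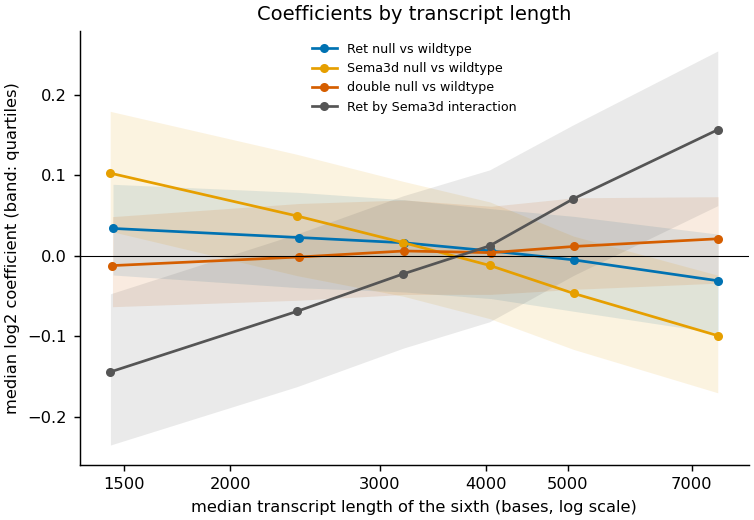
Median log2 coefficient (y axis) of protein-coding genes in 6 equal classes of transcript length (x axis, log scale) for the 3 comparisons with wildtype and the interaction, from the authors' deposited tables. Points are medians and bands the quartiles across genes; the interaction runs from -0.14 to 0.16.

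Genes near the targeted loci were counted because a null allele carries flanking chromosome from the strain in which it was made, and the labels name 3 strains. Within 20 Mb of Ret, 17 of 455 genes were called in Ret null guts (3.74%, against 2.63% elsewhere; Fisher's exact test, two-sided, p = 0.141, adjusted over 4 tests 0.188). In double null guts 17 of 457 were called near Ret (odds ratio 1.83, exact p = 0.0208, adjusted 0.0415) and 13 of 307 near Sema3d (odds ratio 2.09, exact p = 0.0151, adjusted 0.0415). The enrichment near Ret in double null guts did not hold in a window of 50 Mb, but was larger in 1 of 5 Mb (odds ratio 3.13, exact p = 0.00222). In Ret null guts it passed in a window of 5 Mb. Split by direction within 20 Mb in double null guts, higher calls had odds ratios of 5.10 near Ret and 7.69 near Sema3d (exact p = 0.00417 and 7.35e-04). Lower calls had 1.43 and 1.41 (exact p = 0.220 and 0.290). Values for other windows and for the split are not adjusted. In Sema3d null guts 0 of 316 genes near Sema3d were called by the authors' deposited table. Several genes named above lie in these windows: Gxylt2 and Plxnd1 near Ret, and Cd36 and 6030443J06Rik near Sema3d.

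Male and female guts were compared by the sex coefficient of the 24-gut fit, for which the authors' deposited table gives no p-value. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had log2 coefficients, male over female, of 11.19, 10.65, 10.65 and 9.20, and Xist, the RNA that silences one X chromosome in females, -11.26 in the authors' deposited table. Other sex-linked values were smaller, such as -0.65 for Eif2s3x and 0.90 for Xlr3b. Of 12418 genes with a level of at least 50, 21 had a coefficient of at least 1 in size: 4 on Y, 2 on X and 15 elsewhere, 6 of the 21 being pseudogenes. The autosomal genes with the largest coefficients in the authors' deposited table included Pde2a at -2.26, and Afp and Apoa2, which are abundant in fetal liver, at -1.40 and -1.54.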

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

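The tests on enteric neural crest derivatives and on near-identical copies and the removal of the length trend were chosen after the results were seen. The tables give no value per gut, so no gut was examined as standing apart from its group.

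The interaction test of the authors' deposited table found 43 genes whose Ret effect differed between guts with and without Sema3d. Its 20 smallest p-values, all past the adjusted threshold, included genes whose 2 models did not both converge or whose coefficients were unbounded, for which no fold is given. Their interaction coefficients in the authors' deposited table were 7.80 for Gm13394, 9.44 for Gm8276, 60.84 for Gm12191, 33.22 for Gm21985, 10.03 for Gm8210, -10.47 for Rps3a3, -7.44 for Rps3a2 and 115 for Gm28635. Among converged fits the coefficients were 1.28 for Gm9581, -1.70 for Rpl27-ps3, -1.71 for Gm17383, -7.81 for Gm11353 and 1.12 for Gm38372 in the authors' deposited table. The others were 0.88 for Lyst, 0.69 for Klhl11, 0.50 for Pdia4, 0.69 for Farp2, 0.74 for Col12a1, 0.57 for Samd5 and 0.45 for Birc6 in the authors' deposited table.

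For the 34 interaction calls with converged and bounded fits, a trend of the coefficient with transcript length and GC content is a candidate explanation for part of the calls. In 30 of the 34 the trend had the sign of the coefficient, and 8 of the 34 still passed adjusted p 0.05 once it was removed. Their median size fell from 0.691 to 0.544 on the log2 scale, with a median derived error of 0.155, and 30 of the 34 kept a 95% interval that excludes 0, as genes picked for a large coefficient tend to. An interaction in enteric neural crest derivatives stays open: 0 of 4 neural lists passed, but the largest of their median coefficients, that of the progenitor list, was 0.15 with a bootstrap interval over genes of 0.04 to 0.26.

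Pseudogenes made up 9 of the 42 interaction calls with a level of at least 10, against 2.27% of all such genes (Fisher's exact odds ratio 12.0, p = 3.33e-07). Reads shared between near-identical copies may therefore account for this part of the calls. Strain differences in such copies stay open, since they were not tested.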

How the results depend on the processing

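The tables hold no values per gut, so leaving out guts, other splits of the guts, other count models, scalings and pseudocounts, a fit without sex, an estimated correlation, fry and the tests of double null against either single null were not run. No paired analysis was possible because the deposited tables carry no libraries and no replicate numbers. Depth per library is unknown, so its limit on low genes could not be set. The length and GC trend, converged fits and the sex coefficients of single tables were alternatives chosen after seeing the data. Of 275 named gene coefficients compared with the 24-gut fit, 272 moved by less than their derived error and 3 by more, none changing sign. Of 336 list tests under alternatives, 306 stayed on their side of the threshold, 22 no longer passed and 8 newly passed.

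Counts of calls moved by over 1.5 times as follows; stricter or looser thresholds do so by construction. Bonferroni adjustment left 342 Ret null, 5 Sema3d null, 285 double null and 11 interaction calls, and a change of at least 1.5-fold left 422 in Ret null guts. Adjusted p below 0.1 gave 17 in Sema3d null guts and 65 for the interaction, and below 0.01 it gave 5 and 14. With the length and GC trend removed the interaction had 16 calls, 11 positive and 5 negative. Higher calls numbered 95 in Ret null and 57 in double null guts, then 29 and 11 at 1.5-fold, 45 and 21 at adjusted p 0.01, and 12 and 3 by Bonferroni. Lists that passed in Sema3d null guts numbered 7, but 2 with a correlation of 0.05, 2 with members of 1 list only and 4 with the trend removed; the cause was not tested. In double null guts 7 lists passed, and 11 on ranks. For the interaction 1 list passed, and 0 with a correlation of 0.05, on ranks, with members of 1 list only or with the trend removed. The slope of double null on Ret null changes was 1.04 over genes called in the double null and 0.871 over all genes with a level of at least 50, because other genes enter. Shared calls of Ret null and Sema3d null guts numbered 6, then 10 at 0.1 and 3 at 0.01, and those of Sema3d null and double null guts 2, then 6 at 0.1. Genes near Ret had exact p = 0.0106 in a window of 5 Mb in Ret null guts and 0.410 in one of 50 Mb in double null guts; the cause was not tested. Sex coefficients of at least 1 in size numbered 54 in the Sema3d null table, 29 in the Ret null table and 24 in the double null table, against 21 in the 24-gut fit; the cause was not tested.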

Other observations

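The tests of the enteric cell share, of Sema3d loss, of near-identical copies and of the chromosome around Ret were chosen or given their final criteria after the results were seen, and the removal of the length trend was added after seeing the data, with the share of calls to be kept set before that share was computed.

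The pancreas and liver list differed in Sema3d null guts without a called gene. Its members had a median log2 change of 0.49 in Sema3d null, -0.15 in Ret null and 0.08 in double null guts. In the authors' deposited table for Sema3d null guts, Alb, the albumin gene of hepatocytes, had 2.19 ± 1.04, Ttr 0.40 ± 0.13, Serpina1a 0.43 ± 0.16 and the acinar enzyme Cpa1 0.33 ± 0.16. Alpha-globin Hba-a1 had 0.52 ± 0.15 there, and the erythroid list did not pass. The X chromosome silencing RNA Xist had a log2 change of 0.46 ± 0.18 in Ret null guts, adjusted p 0.265 in the authors' deposited table.

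Near Ret, the zinc finger gene Zfp9 was lower and Ankrd26 and Fam21 were higher in both nulls that lack Ret; these were named after their values were seen. Zfp9 changed by -0.46 ± 0.08 in Ret null and -0.32 ± 0.08 in double null guts, and by -0.06 ± 0.13 in Sema3d null guts, in the authors' deposited tables. Ankrd26 changed by 0.27 ± 0.06 and 0.23 ± 0.06, and Fam21 by 0.20 ± 0.06 and 0.19 ± 0.06, in the authors' deposited tables. On chromosome 4 the neighbours Alad and Hdhd3, also named after their values were seen, were higher in Ret null guts, at 0.90 ± 0.15 and 1.12 ± 0.28 in the authors' deposited table.

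Endothelial genes were higher in double null guts, and 7 of 7 called list genes still passed with the length and GC trend removed, which argues against that trend as the whole cause. A smaller share of enteric cells would raise other cell types alike, and alike in Ret null guts, whose neuron list median was -2.50 against -2.61 in double null guts. Against it, the endothelial median exceeded that of 91 genes of 6 other non-neural lists by 0.160 (bootstrap interval over genes 0.131 to 0.220). In the 24-gut fit the endothelial median was 0.0328 in Ret null minus wildtype. In double null minus Ret null it was 0.217 (interval 0.135 to 0.244, 15 of 15 genes positive). With the trend removed these medians were -0.00899 and 0.239 (0.170 to 0.281). The intervals and the count of positive genes rest on genes of the same guts, so the spread between guts was not measured. The loss of Sema3d, with or without Ret, is a candidate explanation that rests in part on the same values: the median in Sema3d null minus wildtype was 0.213, and with the trend removed the list median in the Sema3d null table was 0.145 (list adjusted p = 3.17e-04). In list tests against wildtype with the trend removed, pancreas and liver passed in Sema3d null guts too (adjusted p = 0.00291). The erythroid, macrophage and hypoxia lists did not (0.363, 0.255 and 0.255), and none of these 4 passed in double null guts. In double null minus Ret null with the trend removed, their medians were 0.314, 0.253, 0.203 and 0.193 in that order, with intervals above 0. Smooth muscle, epithelium and mesothelium had 0.0257, 0.0480 and 0.00817. The difference between double null and Ret null guts was therefore not particular to endothelial genes. Before trend removal, pancreas and liver, erythroid, macrophage and hypoxia had Ret null minus wildtype medians of -0.192, -0.226, -0.226 and -0.0706. Their double null minus wildtype medians were 0.123, 0.0932, -0.0555 and 0.0983, against 0.226 for endothelium. At the median these lists lay below wildtype in Ret null guts and did not rise over wildtype as far as endothelial genes. Of the 7 called list genes 0 lay within 50 Mb of Ret or Sema3d, while litter, dissection and effects of flanking genes on distant ones stay open.

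Genes higher in Ret null guts held 9 pseudogenes among 95, against 8 among the 559 lower genes (Fisher's exact odds ratio 7.21, p = 1.80e-04), so reads shared between near-identical copies may account for part of them. The length and GC trend as the whole cause is argued against by 72 of 93 calls that still passed after its removal. Flanking chromosome could not be decided: 3 of the 95 lay within 20 Mb of Ret (odds ratio 1.72, exact p = 0.260). A response of the gut wall to the missing enteric cells stays open and was not tested.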
